A study of Mus musculus with 21 samples.

How the data were processed

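Poly(A) RNA of sorted cells was captured on oligo(dT) beads, amplified as cDNA with a kit that adds no molecular identifiers (NuGEN Ovation RNA-Seq V2) and made into Nextera XT libraries, per the labels' protocols. Amplified reads are not independent molecules, so counting intervals and floors cover counting error only. Epithelium of small intestine, colon and gall bladder was released with EDTA, thymus was digested with Liberase and DNase and enriched on Percoll, and trachea was treated with Dispase and trypsin, per the labels' protocols. The study sorted 4 replicates of each group and discarded 1 small intestine tuft, 1 gall bladder tuft and 1 non-tuft replicate for failed quality control, per the series description. Mice were 12-week-old males, except that trachea pools of 4 mice were 12 to 16 weeks old and pools 3 and 4 were female. In the trachea libraries Xist was at 4628 and 4975 CPM in the pools labelled female and at 2.87 and 6.45 CPM in those labelled male.

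The deposited files hold whole-number counts per gene and library, with no normalization, for 43432 gene identifiers. The submitters' processing notes name STAR, DESeq2 and the mouse genome build GRCm38; their versions, the counting step, its use of strand and the annotation are not given in the sources used here. Identifiers were matched to GENCODE M21, the source of symbols and coordinates: 42548 matched and 884 did not, the latter with 0.099% of counts. Of 13 mitochondrial transcripts listed, 8 had enough counts to be tested; why the others were near 0 is not given in the sources used here. Reads of near-identical paralogs and of overlapping or antisense genes could not be told apart. Each library was counted as 1 sample because the labels name it as a separate replicate. A check for repeat deposits of the same library found no pair within a group whose counts lay within sampling noise, and separate mice or pools would exceed that noise in any case.

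Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1, with DESeq2 1.42.0 as an alternative, and in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9. Genes were filtered with filterByExpr, scaled by TMM and tested with the quasi-likelihood F test on trended dispersions (glmQLFit with legacy = TRUE), two-sided, with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05 and an absolute log2 fold change of at least 1. Standard errors of log2 fold changes were taken as the fold change over the square root of F and are approximate. Levels are CPM, counts scaled by TMM to a common library total, as mean ± SD over libraries. Small intestine tuft and non-tuft cells were compared in a fit of 6 libraries. Each tissue was set against the unweighted mean of the other 4 in a fit of the 18 tuft libraries (19850 genes tested). A gene was restricted to a tissue when called higher there than in each of the other 4, and shared when called higher in all 5 tissues than in the reference in a fit of 21 libraries.

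The 31 gene lists, 13 of functions and 18 of cell type markers, were written down before the data were examined, as were the design, the rule for named genes and most alternatives. Lists were tested with camera at a preset correlation of 0.01 and with an estimated one, and with fry, which asks whether a list moves on balance one way and compares it with no other genes; p-values were adjusted over 370 tests. Of the 105 camera calls in the 7 main comparisons, 23 held with an estimated correlation. The rule named, for tuft against non-tuft cells, the 10 largest changes each way among called genes with a mean of at least 20 CPM in the higher group and no overlap between libraries of both groups. It named 5 each way for colon against small intestine tuft, and 6 restricted genes per tissue and 10 shared genes by the smallest of their changes, with the same minimum level. Predicted genes, Xist, Y-linked genes and antigen receptor segments were left out of the ranks. Members of the lists could also be named, and Sucnr1, Il25, Pou2f3, Trpm5 and Dclk1 were always given. A gene that the rule named is not reported here.

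The fit was tested on simulated counts with 200 changed genes, 100 at 2-fold and 100 at 4-fold. A 2-fold change lies at the call threshold, so its share called is held down by the rule as well as by the spread. For small intestine tuft against non-tuft cells, 53% of 2-fold and 100% of 4-fold changes were called, with 11 unchanged genes among 164 calls (15555 genes). For gall bladder the shares were 4% and 38%, with 3 of 45 calls unchanged (19416 genes), for trachea 8% and 42%, with 2 of 52 (19402 genes), and for the shared signature 0% and 19%, with 0 of 19 (19893 genes). Each simulated gene had 1 dispersion in all groups. The measured relative spread between replicates was 0.198 in the reference, 0.298 in small intestine tuft, 0.738 in gall bladder tuft and 0.748 in trachea tuft. Shares and false calls in the noisiest groups may therefore differ from these. The default dispersion of edgeR 4 called 39 unchanged genes among 92 in gall bladder and 25 among 82 in trachea, so trended dispersions were used after this test. The simulated counts were drawn with dispersions from the same estimate as the trended fit, which may favour it. Alternatives were DESeq2 size factors (RLE), no filter, a filter of 5 CPM in 3 libraries, the DESeq2 test, limma voom with sample weights, no fold threshold, other libraries in the fit, a replicate block, thinning to the lowest total, male trachea pools alone and each replicate left out. Chosen after seeing the data were leaving out mitochondrial genes, leaving out trachea libraries and the edgeR 4 default.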

Results

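Messenger RNA was sequenced from tuft cells, a rare chemosensory epithelial cell type, sorted from 5 mouse tissues. The mice carried a fluorescent reporter in the Il25 gene (Flare25), so that live CD45-negative, EPCAM-positive cells with reporter signal could be taken as tuft cells. The 21 libraries fell into 6 groups. These were small intestine tuft (n = 3), colon tuft (n = 4), gall bladder tuft (n = 3), thymus tuft (n = 4), trachea tuft (n = 4) and reporter-negative small intestine epithelium, the non-tuft reference (n = 3). Trachea libraries were pools of 4 mice and the others came from 1 mouse each. Summed gene counts ranged from 25739248 to 73574745 per library. The number of sorted cells differed far more. It was 130 to 453 in trachea, 1350 to 1900 in thymus, 1750 to 2700 in gall bladder and 13500 to 16000 in colon. It was 35000 to 36000 in small intestine tuft and 52000 to 57000 in the reference. Non-tuft cells were measured in the small intestine alone, and thymus and trachea were each dissociated by a protocol of their own, so tissue and preparation could not be separated.

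Each library correlated more closely with its own group than with any other group. The mean correlation of log2 CPM between replicates was 0.979 in the reference, 0.96 in small intestine tuft, 0.941 in colon tuft, 0.884 in thymus tuft, 0.866 in gall bladder tuft and 0.848 in trachea tuft. CPM stands for gene counts scaled to a common library total. Mitochondrial transcripts took 24.1 to 33.5% of counts in small intestine tuft and 4.38 to 5.97% in thymus tuft. Principal components 1 and 2 held 38.7% and 27.6% of the variance of the most variable genes.

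**Figure D1:**
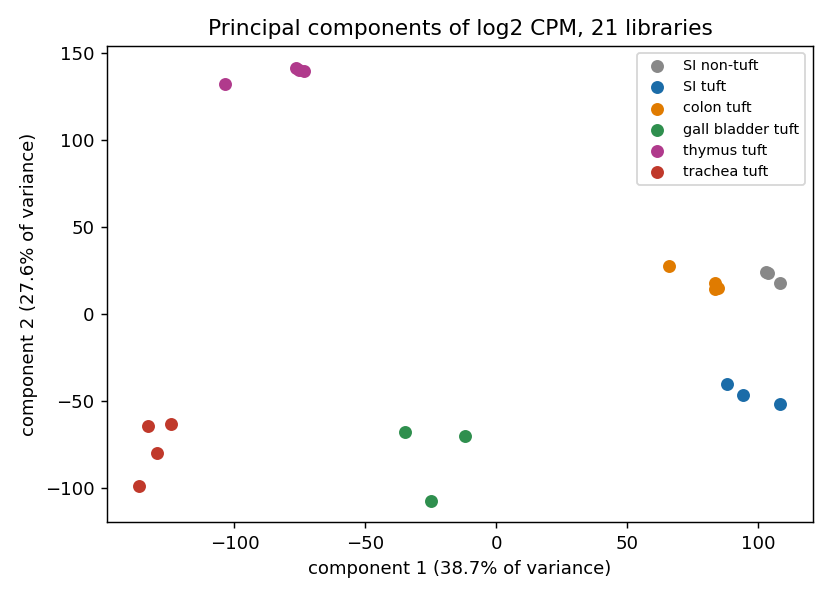
Principal components of log2 CPM over the 21 libraries, with component 1 (38.7% of variance) on the horizontal and component 2 (27.6%) on the vertical axis, and each point 1 library coloured by group. Thymus, trachea and gall bladder tuft libraries lie apart from each other, while colon and small intestine tuft libraries lie on the side of the reference (SI non-tuft) on component 1. On component 2 colon tuft libraries (14.38 to 27.39) lie by the reference (17.6 to 23.93), and small intestine tuft libraries at -40.28 to -52.1.

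The comparison of tuft with non-tuft cells of the small intestine asked which genes mark the tuft cell within 1 epithelium. Pou2f3, the transcription factor that tuft cells need to form (ENSMUSG00000032015, GRCm38 chromosome 9, 43123939 to 43210369), was at 621 ± 98.2 CPM (SD, n = 3) in tuft and 12.4 ± 1.88 (SD, n = 3) in non-tuft cells. Trpm5, the cation channel of taste signalling (ENSMUSG00000009246, chromosome 7, 143069153 to 143094642), was at 4713 ± 693 and 42.9 ± 22.3 CPM. The kinase gene Dclk1 (ENSMUSG00000027797, chromosome 3, 55242364 to 55539068) was at 2303 ± 262 and 26.2 ± 3.94 CPM. Sucnr1, the succinate receptor (ENSMUSG00000027762, chromosome 3, 60081869 to 60087566), was at 23.3 ± 4.07 and 0.58 ± 0.319 CPM. Il25 (ENSMUSG00000040770, chromosome 14, 54932695 to 54935837) was at 23.9 ± 2.61 and 0.277 ± 0.151 CPM. The cells were sorted on a reporter in Il25, so that difference is no independent result. The log2 fold changes were 5.75 ± 0.19 (SE) for Pou2f3, 6.87 ± 0.38 for Trpm5, 6.55 ± 0.19 for Dclk1 and 5.43 ± 0.40 for Sucnr1. Their adjusted p ran from 2.38e-08 for Dclk1 to 4.25e-06 for Sucnr1 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment).

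**Figure D2:**
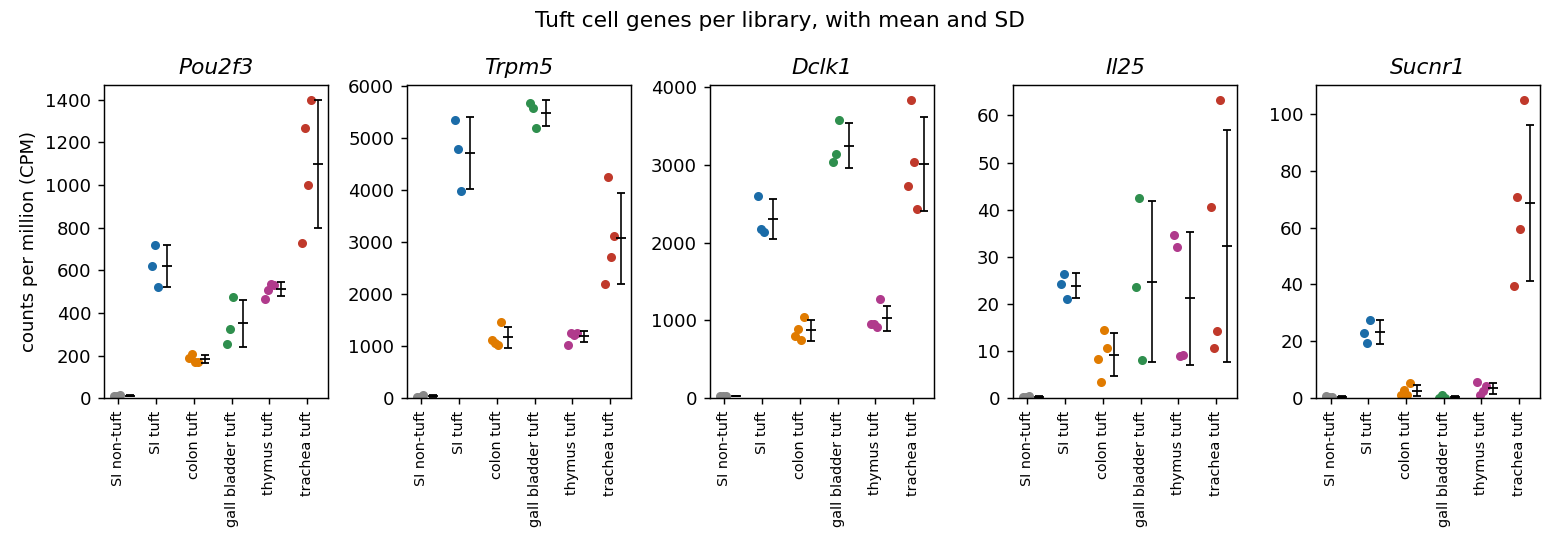
CPM of Pou2f3, Trpm5, Dclk1, Il25 and Sucnr1 in each library (coloured points), with the mean and SD of each group in black, on linear axes that start at 0. Sucnr1 is at 68.6 CPM on average in trachea tuft and 23.3 in small intestine tuft, and at or under 3.46 in colon, gall bladder and thymus tuft.

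All 40 members of the tuft core list, Il25 among them, rose (40 adjusted over the list alone). The list stood above other genes (camera adjusted p = 2.93e-29), a call that was lost at adjusted p = 0.078 with an estimated correlation. The 10 largest increases by the rule for named genes were those of Glis1, Cnih3, Nrgn, Sema6c, Col15a1, Folr1, Dnah6, Rgs13, Ly6g6f and Car7. Glis1, which encodes a zinc finger protein (ENSMUSG00000034762, chromosome 4, 107434591 to 107635061), was at 33.1 ± 4.13 against 0.203 ± 0.156 CPM. Rgs13, a regulator of G protein signalling, was at 741 ± 289 against 6.39 ± 1.01 CPM. Haematopoietic signalling genes, usually associated with blood cells, rose in 15 and fell in 2 of 25 measured members (the same numbers adjusted over the list alone). Ptprc, which encodes CD45, was at 144 ± 18.8 and 6.3 ± 3.5 CPM, although CD45-positive cells were excluded by the sort. The camera adjusted p of this list was 7.43e-08, and adjusted p = 0.0248 with an estimated correlation. Thymocyte and T cell markers were higher in 4 and lower in 0 of 7 (4 adjusted over the list alone; camera adjusted p = 0.0659), with Cd3e at 10.5 ± 3.48 against 1.71 ± 1.02 CPM. Myeloid markers were higher in 3 and lower in 0 of 11 (2 adjusted over the list alone; camera adjusted p = 0.205), with Tyrobp at 5 ± 1.38 against 0.874 ± 0.587 CPM. Of 17 eicosanoid genes, 8 rose and 1 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.0029, and adjusted p = 0.0952 with an estimated correlation).

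Among these, Alox5 (949 ± 80 against 9.31 ± 2.56 CPM), Ptgs1 (760 ± 118 against 11.6 ± 0.516 CPM) and Hpgds (112 ± 28 against 3.8 ± 0.932 CPM) encode enzymes that make leukotrienes and prostaglandins. Taste transduction genes rose in 5 of 12 (5 adjusted over the list alone; camera adjusted p = 0.0292, and adjusted p = 0.234 with an estimated correlation). Metabolite and lipid receptors rose in 3 and fell in 9 of 18 (the same adjusted over the list alone; camera adjusted p = 0.0212 in the lower direction, and adjusted p = 0.224 with an estimated correlation). Ffar3, a receptor of short-chain fatty acids, was at 610 ± 45.3 against 6.37 ± 1.61 CPM. Dissociation stress genes fell in 9 of 21 (9 adjusted over the list alone; camera adjusted p = 0.00336, and adjusted p = 0.336 with an estimated correlation), with Fos at 301 ± 18.4 against 1108 ± 53.7 CPM.

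Markers of the other secretory cells fell in tuft cells. All 10 goblet genes, 12 Paneth genes and 19 enteroendocrine genes measured were lower (the same numbers adjusted over each list alone). The camera adjusted p was 6.44e-09, 2.96e-07 and 1.93e-09, and adjusted p = 0.0948, 0.211 and 0.0826 with an estimated correlation. Zg16, a goblet cell lectin (ENSMUSG00000049350, chromosome 7, 127050156 to 127087328), was at 445 ± 61.3 against 25680 ± 1570 CPM. Chga, an enteroendocrine granule protein, was at 35 ± 5.67 against 519 ± 112 CPM, and Mmp7, a Paneth cell protease, at 4.86 ± 2.54 against 271 ± 23.6 CPM. The 10 largest decreases by the rule were those of Mptx2, Defa29, AY761184, Zg16, Defa26, Nts, Mmp7, Defa30, Fer1l6 and Defa24. The Defa genes and AY761184 are near-identical copies, so their separate counts are uncertain. Proliferation genes fell in 25 of 26 (25 adjusted over the list alone), with Mki67 at 213 ± 58.4 against 775 ± 96.2 CPM (camera adjusted p = 7.4e-11, and adjusted p = 0.124 with an estimated correlation).

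Enterocyte genes did not fall. Of 20, 2 rose (2 adjusted over the list alone) and the other 18 passed in neither direction, and their median log2 ratio was 0.65 (camera adjusted p = 2.69e-04, and adjusted p = 0.19 with an estimated correlation). Fabp1, a fatty acid binding protein of absorptive cells, was at 5434 ± 755 in tuft and 1217 ± 233 CPM in non-tuft cells. Of 9 measured airway secretory genes, 6 were higher in the tuft libraries (7 adjusted over the list alone; camera adjusted p = 0.0977). Scgb1a1, a club cell gene, was at 33.1 ± 32.8 and 0.969 ± 0.137 CPM, with 65.8, 33.3 and 0.233 CPM in tuft libraries 2, 3 and 4. In total 2092 genes were higher and 2235 lower of 16063 tested, at an adjusted p under 0.05 and a fold of at least 2. With all 21 libraries in the fit the counts were 785 and 539.

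**Figure D3:**
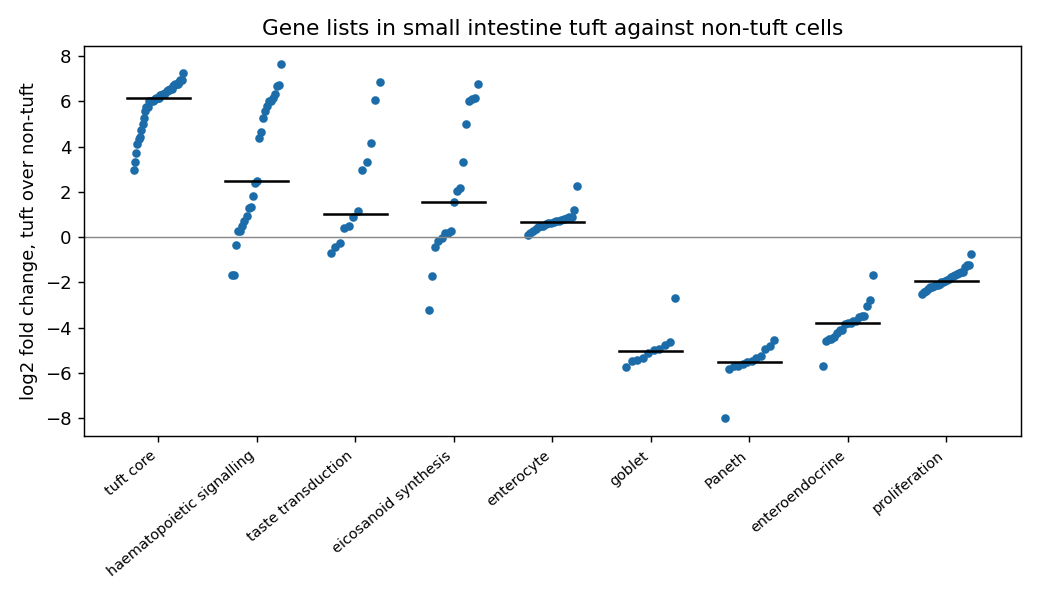
Log2 fold changes of the genes of 9 fixed lists in small intestine tuft over non-tuft cells, each point 1 gene and each black line the median of its list. Tuft core genes lie above 0, goblet, Paneth, enteroendocrine and proliferation genes below, and enterocyte genes lie near a median of 0.65.

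Tuft cells of the 5 tissues were next set against the reference to find what they had in common. A total of 266 genes of 20335 tested were called higher in every tissue, and 37 of the 40 tuft core genes were among them. The genes named by rule included Fyb, Pstpip1, Dclk1, Pik3cg, Chat, Nxpe2, Hmx3, Pnpla3 and Alox5. Fyb (ENSMUSG00000022148, chromosome 15, 6522853 to 6663313) encodes an adaptor protein of T cells, and Chat the enzyme that makes acetylcholine. The smallest log2 fold change over the 5 tissues was 5.19 for Fyb and 4.83 for Alox5. Fyb was at 551 ± 71.6 CPM (SD, n = 4) in colon and 2355 ± 636 (SD, n = 3) in gall bladder tuft against 14 ± 2.8 in the reference. Chat was at 134 ± 41.4 in thymus and 434 ± 89.4 in gall bladder tuft against 3.91 ± 0.558. All 5 contrasts used the same 3 reference libraries. Simulated groups with no change against those libraries gave 0 shared genes in each of 10 sets, and independent lists of the observed lengths would share 0.103. No gene was changed in any simulated tissue, while 785 to 3488 genes per tissue were called higher in the data. The simulation thus cannot size the overlap that shared controls give. The reference could not be split, so part of the excess may come from shared controls, and outside the small intestine the contrast also holds the difference between organs.

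Small intestine tuft libraries were higher than the other tuft libraries in genes of absorptive epithelium, and markers of other intestinal cells were higher with them. No test separated tuft cells from enterocyte RNA or cells in the sort as the source of the absorptive genes. Lct, which encodes lactase (ENSMUSG00000026354, chromosome 1, 128284756 to 128328318), was at 638 ± 58.7 CPM (SD, n = 3) and at 5.38 ± 4.76 (SD, n = 4) in thymus tuft, the next highest. The transporter genes Slc5a12, Slc5a11, Slc5a4a and Slc5a4b and the sulfotransferase gene Sult6b2 were also named by rule. Slc5a4a and Slc5a4b are closely similar neighbours with uncertain counts. Lct was at 444 ± 24 CPM in non-tuft cells, and Slc5a12 was at 32.1 ± 2.46 in tuft and 32.7 ± 8.14 in non-tuft cells. Of the 205 genes restricted to small intestine tuft, 54 were higher, 6 lower and 145 neither against non-tuft cells. All 20 enterocyte genes were higher than the mean of the other tissues (20 adjusted over the list alone; camera adjusted p = 7.07e-25, and adjusted p = 0.0025 with an estimated correlation). Tuft core genes were higher in 24 and lower in 2 of 40 (the same adjusted over the list alone; camera adjusted p = 1.2e-12, and adjusted p = 0.0529 with an estimated correlation). Il17rb, a subunit of the IL-25 receptor, was at 687 ± 101 CPM here and between 157 and 256 in the other tissues. Enteroendocrine genes were higher in 12 of 19 (13 adjusted over the list alone; camera adjusted p = 9.03e-06, and adjusted p = 0.0566 with an estimated correlation), with Chga at 35 ± 5.67 CPM, and Paneth genes were higher in 7 and lower in 1 of 10 (the same adjusted over the list alone; camera adjusted p = 0.0645). Proliferation genes were higher in 12 of 26 (13 adjusted over the list alone; camera adjusted p = 3.33e-07, and adjusted p = 0.0817 with an estimated correlation). Dissociation stress genes were lower in 10 of 21 (11 adjusted over the list alone; camera adjusted p = 9.68e-05, and adjusted p = 0.191 with an estimated correlation).

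All 8 measured mitochondrial transcripts were higher in small intestine tuft too (8 adjusted over the list alone; camera adjusted p = 1.62e-08, and adjusted p = 0.0993 with an estimated correlation). In total 1991 genes were higher and 1478 lower. DESeq2 gave 1846 and 2497, and a filter of 5 CPM in 3 libraries 1403 and 1552. Without small intestine library 2, 3 or 4 the number lower was 923, 873 or 829.

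Colon tuft libraries held genes of the distal bowel. Whether tuft cells or other colon cells in the sort held them was not tested. Hoxb13, a homeobox gene of the hindgut (ENSMUSG00000049604, chromosome 11, 96194316 to 96197447), was at 57.2 ± 24.1 CPM (SD, n = 4) and at 0.553 ± 0.66 (SD, n = 4) in thymus tuft, the next highest. Car1, a carbonic anhydrase of colonocytes, was at 875 ± 360 and 7.19 ± 2.6 CPM. Mptx1, Tat, Gsdmcl2 and Cyp2d34 completed the genes named by rule, of which Gsdmcl2 and Cyp2d34 have close paralogs and are uncertain. Of 10 colonocyte genes 9 were higher (10 adjusted over the list alone; camera adjusted p = 1.03e-14, and adjusted p = 0.00141 with an estimated correlation). Proliferation genes were higher in 22 of 26 (22 adjusted over the list alone; camera adjusted p = 8.92e-16, and adjusted p = 0.011 with an estimated correlation), with Mki67 at 627 ± 124 CPM. Tuft core genes were lower in 25 and higher in 1 of 40 (26 and 1 adjusted over the list alone; camera adjusted p = 6.17e-17, and adjusted p = 0.0248 with an estimated correlation). Trpm5 was at 1170 ± 206 and Pou2f3 at 183 ± 19.3 CPM. Goblet genes were higher in 6 of 11 (8 adjusted over the list alone; camera adjusted p = 8.57e-05, and adjusted p = 0.256 with an estimated correlation), with the mucin gene Muc2 at 5194 ± 1220 CPM. Dissociation stress genes were higher in 8 and lower in 0 of 21 (8 and 0 adjusted over the list alone; camera adjusted p = 4.87e-04, and adjusted p = 0.239 with an estimated correlation). In total 2122 genes were higher and 1148 lower, and 123 were restricted to colon tuft. DESeq2 gave 2000 and 1895, and without small intestine library 2, 3 or 4 the restricted genes numbered 76, 70 or 74.

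Set directly against small intestine tuft cells, colon tuft cells were lower in 35 of 40 tuft core genes (37 adjusted over the list alone; camera adjusted p = 6.22e-34, and adjusted p = 0.00381 with an estimated correlation). Dclk1 was at 872 ± 131 against 2303 ± 262 CPM, a log2 fold change of -1.43 ± 0.19 (SE), and Sucnr1 at 2.67 ± 1.97 against 23.3 ± 4.07 CPM. No colon non-tuft cells were measured, so lower levels in tuft cells could not be told apart from other cells in the colon sort. The mean correlation of colon tuft libraries was 0.885 with the reference and 0.877 with small intestine tuft. The enterocyte genes were lower in 18 of 20 (20 adjusted over the list alone; camera adjusted p = 1.06e-28, and adjusted p = 0.00197 with an estimated correlation). Dissociation stress genes were higher in 12 of 21 (12 adjusted over the list alone; camera adjusted p = 2.79e-08, and adjusted p = 0.0817 with an estimated correlation). By the rule, Mptx1, Slc6a14, Tgm3, Lpo and Arhgap20 were named as higher and Prkcb, Cnih3, Akp3, Lct and Dao as lower. A total of 885 genes were higher and 775 lower. Over the 10 tissue pairs, ranked in this fit alone, totals ran from 1660 here to 6074 between gall bladder and thymus. DESeq2 gave 1607 higher and 1116 lower here, and limma voom with sample weights 2661 and 2390. Without small intestine library 2, 3 or 4 the number higher was 491, 460 or 456, and without library 2 the number lower was 506.

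Gall bladder tuft libraries held genes of biliary epithelium. Whether tuft cells or other gall bladder cells in the sort held them was not tested. Sox17, a transcription factor of the developing biliary tract (ENSMUSG00000025902, chromosome 1, 4490931 to 4497354), was at 67.4 ± 6.92 CPM (SD, n = 3) and at 0.104 ± 0.079 (SD, n = 4) in thymus tuft, the next highest. Rasgrf1 and Rasgrp3, exchange factors of Ras family proteins, were at 243 ± 190 and 90.6 ± 43.5 CPM. Lrg1, Ildr2 and the transcription factor gene Onecut1 were also named by rule. Of 14 cholangiocyte and gall bladder genes 9 were higher and 1 lower (the same adjusted over the list alone; camera adjusted p = 4.6e-08, and adjusted p = 0.0204 with an estimated correlation), with the mucin Muc1 at 1571 ± 176 and Spp1 at 261 ± 111 CPM. Tuft core genes were higher in 20 and lower in 2 of 40 (the same adjusted over the list alone; camera adjusted p = 3.15e-10, and adjusted p = 0.0826 with an estimated correlation). Casr, the calcium-sensing receptor, was at 141 ± 114 CPM against 0.293 ± 0.0806 in colon tuft. It was not restricted to gall bladder tuft, and nor was any other metabolite or lipid receptor listed. Sucnr1 was at 0.458 ± 0.43 CPM, a log2 fold change of -4.58 ± 0.80 (SE) against the mean of the other tissues (adjusted p = 0.000407, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Dissociation stress genes were higher in 8 and lower in 1 of 21 (9 and 1 adjusted over the list alone; camera adjusted p = 8.78e-05, and adjusted p = 0.19 with an estimated correlation). In total 2521 genes were higher and 1744 lower, and 184 were restricted to gall bladder tuft. DESeq2 gave 2384 higher and 3328 lower, and limma voom with sample weights 1631 and 607. Without small intestine library 2, 3 or 4 the restricted genes numbered 104, 115 or 106. They numbered 102 with the replicate block, 311 with limma voom and 631 without trachea libraries.

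Thymus tuft cells had the most restricted genes. All 29 bitter taste receptor genes were higher than the mean of the other tissues (29 adjusted over the list alone; camera adjusted p = 9.58e-17, and adjusted p = 0.0043 with an estimated correlation). Of these 29, the members of 35 listed that passed the filter, 10 were restricted to thymus tuft and 1 to trachea tuft. In the small intestine fit 1 of the 35 passed, so the 29 were largely those with counts in other tissues, thymus among them. That all 29 were higher in thymus tuft, and the camera result with it, was therefore partly built in by the filter. Tas2r108, higher still in trachea tuft, was at 44.1 ± 5.23 and Tas2r105 at 8.08 ± 2.96 CPM (SD, n = 4). All 12 genes of the MHC class II pathway, which presents antigen to T cells, were higher (12 adjusted over the list alone; camera adjusted p = 1.47e-10, and adjusted p = 0.0474 with an estimated correlation), with Cd74 at 4852 ± 1060 CPM and at 249 ± 183 in colon tuft. All 17 thymic epithelial genes were higher (17 adjusted over the list alone; camera adjusted p = 4.17e-10, and adjusted p = 0.0166 with an estimated correlation), with Aire, a regulator of tissue antigen expression in the thymic medulla, at 232 ± 45.2 CPM. By the rule, Ifi211 (ENSMUSG00000026536, chromosome 1, 173896345 to 173913046), Galnt14, Gucy2e, Col6a2, Col6a1 and Skint1 were named, the last with close paralogs and so uncertain.

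Markers of other cells moved with these groups. Stromal genes were higher in 14 of 15 (14 adjusted over the list alone; camera adjusted p = 3.25e-08, and adjusted p = 0.00381 with an estimated correlation) and myeloid genes in 9 of 14 (10 adjusted over the list alone; camera adjusted p = 0.00149, and adjusted p = 0.0216 with an estimated correlation). Ciliated cell genes were higher in 12 of 15 (12 adjusted over the list alone; camera adjusted p = 8.37e-04, and adjusted p = 0.193 with an estimated correlation), with Foxj1 at 59.8 ± 24.5 CPM. Thymocyte and T cell genes were higher in 11 of 15 (12 adjusted over the list alone; camera adjusted p = 0.00965, and adjusted p = 0.318 with an estimated correlation), with Cd3e at 1.72 ± 2.24 CPM. The 8 mitochondrial transcripts were lower (8 adjusted over the list alone; camera adjusted p = 1.48e-10, and adjusted p = 0.0698 with an estimated correlation). In total 5316 genes were higher and 1119 lower, and 1228 were restricted to thymus tuft, with a median level of 6.8 CPM. With a filter of 5 CPM in 3 libraries the numbers were 2651 higher, 1107 lower and 661 restricted. Without small intestine library 2, 3 or 4 the restricted genes numbered 816, 801 or 792.

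Trachea tuft cells were high in taste signalling. Gnat3, which encodes the taste G protein gustducin, was at 5554 ± 2040 CPM (SD, n = 4) and at 607 ± 159 (SD, n = 4) in thymus tuft. Its partner Gnb3 was at 958 ± 338 and 196 ± 16 CPM. Of 14 taste transduction genes 7 were higher and 2 lower (the same adjusted over the list alone; camera adjusted p = 5.82e-04, and adjusted p = 0.0826 with an estimated correlation). Of 29 bitter receptors 17 were higher (17 adjusted over the list alone; camera adjusted p = 0.00689, and adjusted p = 0.259 with an estimated correlation), with Tas2r108 at 216 ± 88.2 CPM. Sucnr1 was at 68.6 ± 27.5 CPM, a log2 fold change of 4.4 ± 0.46 (SE; adjusted p = 5.38e-07, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Nkx2-1, a transcription factor of the airway (ENSMUSG00000001496, chromosome 12, 56531958 to 56536908), was at 168 ± 55.6 CPM, and the transcription factor gene Tbx1 at 45.4 ± 14.6 CPM. Scgb3a1, Scgb3a2, Sult1c1 and Pon1 completed the genes named by rule.

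All 12 airway secretory cell genes were higher in trachea tuft as well (12 adjusted over the list alone; camera adjusted p = 4.82e-13, and adjusted p = 0.0488 with an estimated correlation), with Scgb1a1 at 23620 ± 20500 CPM. Basal cell genes were higher in 8 of 10 (8 adjusted over the list alone; camera adjusted p = 0.00314, and adjusted p = 0.202 with an estimated correlation). MHC class II genes were lower in 11 and higher in 1 of 12 (the same adjusted over the list alone; camera adjusted p = 6.47e-06, and adjusted p = 0.136 with an estimated correlation). In total 3436 genes were higher and 2711 lower, and 362 were restricted to trachea tuft. DESeq2 gave 3371 and 3689, and limma voom with sample weights 1852 and 1547. The restricted genes numbered 283 with the replicate block and 700 with the edgeR 4 default dispersion.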

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

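All tests in this part were planned. In the groups of 4 libraries, 78 measures were looked at for 1 library far from the rest, by its gap to the nearest library as a share of the whole range (Dixon test). Chance flags about 1 in 20 groups, or 3.9 of 78, and 4 were found, so their number is no more than chance gives. Pstpip1 was at 53.1 CPM in thymus tuft library 3 and between 30.7 and 33 in the others. Dclk1 was at 1269 CPM in thymus tuft library 4 and between 920 and 959 in the others. Sult1c1 was at 176 CPM in trachea tuft library 3 and between 9.52 and 21.7 in the others. Scgb3a2 was at 7452 CPM in trachea tuft library 1 and between 2202 and 2903 in the others. No explanation of these was tested.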

How the results depend on the processing

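Alternatives without mitochondrial genes, without trachea libraries and with the edgeR 4 default dispersion were chosen after the data were seen, the others before. For the 75 named results, 1975 of 1976 values under alternatives kept direction and call; Defa29 had an adjusted p of 0.0723 with all 21 libraries in the fit, and DESeq2 gave no adjusted p for 3 (Lct in 2 comparisons, Tgm3). None was reversed. The cause of the changes below was not tested, except where fewer libraries or genes entered by construction. Small intestine tuft against non-tuft gave 3475 higher and 3513 lower genes by adjusted p alone, 785 and 539 with 21 libraries in the fit, and 1411 lower under the stricter filter, which left 2651 thymus genes higher and 661 restricted. DESeq2 gave 2497, 1895 and 3328 genes lower in small intestine, colon and gall bladder tuft, 198 and 288 restricted to colon and gall bladder, and 1607 higher in colon than small intestine tuft; its share of higher calls was 42.5, 51.3 and 41.7% in the first 3, against 57.4, 64.9 and 59.1%, and 47.7% in trachea against 55.9%. The stricter filter gave 47.5% in small intestine. RLE scaling moved the median of all genes by 0.105 in thymus tuft and by 0.221 in thymus tuft against the reference (log2); voom moved it by 0.191 in small intestine and -0.129 in trachea tuft, and by -0.144 and -0.242 in gall bladder and trachea tuft against the reference. The edgeR 4 default gave 393, 285, 494 and 700 genes restricted to small intestine, colon, gall bladder and trachea. Voom gave 3706 higher and 2949 lower in small intestine, 1782 lower in colon, 1631 and 607 in gall bladder, 1852 and 1547 in trachea, 527, 456, 311 and 1859 restricted to small intestine, colon, gall bladder and thymus, and 2661 higher and 2390 lower in colon than small intestine tuft. Without trachea libraries 2920 and 2130 genes were lower in gall bladder and thymus, 348, 292, 631 and 2121 restricted to small intestine, colon, gall bladder and thymus, and 1411 higher and 1186 lower in colon than small intestine tuft. Leaving out 1 library in turn gave 829 to 1577 genes lower in small intestine, 70 to 157 restricted to colon, 104 to 237 to gall bladder and 792 to 1296 to thymus, and 456 to 1041 higher and 506 to 892 lower in colon than small intestine tuft; all moves over 1.5 times came from leaving out small intestine tuft library 2, 3 or 4.

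The replicate block gave 1326 higher, 1132 lower and 102 restricted genes in gall bladder tuft and moved no other count given in the report over 1.5 times. Whether the numbers pair libraries stayed open. Of 28 pairs with the same number none had a correlation of deviations over 0.1 (-0.067 to 0.09). The mean was 0.007, against -0.002 in the 87 pairs with other numbers. Yet 9 of 17 libraries correlated best with their own number. Among thymus tuft libraries, each colon tuft library correlated best with that of its own number (0.09, 0.046, 0.089 and 0.047). The reach of the test was limited in gall bladder and trachea, where 38% and 42% of simulated 4-fold changes were called. It was lowest for the shared signature, at 19%. These shares come from a simulation with 1 dispersion per gene in all groups.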

Other observations

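Several genes of lipid mediators and cytokines were high in thymus and trachea tuft libraries. Markers of other cells were higher in the same libraries, with 9 of 14 myeloid genes in thymus (camera adjusted p = 0.00149, and adjusted p = 0.0216 with an estimated correlation) and 12 of 12 airway secretory and 8 of 10 basal genes in trachea. Which cells held the transcripts below was not tested. Alox15, a lipoxygenase gene, was at 109 ± 23.6 CPM (SD, n = 4) in thymus and 95 ± 47.9 (SD, n = 4) in trachea tuft, and at or under 2.08 in the other 3 tissues. Ptges, a prostaglandin E synthase gene, was at 67.4 ± 19.8 and 30.9 ± 36.2 CPM and at or under 0.48 elsewhere, and the cytokine gene Il10 at 60.8 ± 9.79 and 15.4 ± 10.1 CPM and at or under 0.498 elsewhere. These 3 genes were called higher in thymus and in trachea tuft than the mean of the other 4 tissues (edgeR quasi-likelihood). Thymus tuft was also called higher for Cysltr2, a leukotriene receptor gene (51.3 ± 12.2 CPM), Ptgs2, a cyclooxygenase gene (403 ± 36.5 CPM), and Ache, which encodes the enzyme that breaks down acetylcholine (225 ± 57.5 CPM). Ffar3 ran the other way, at 610, 155 and 286 CPM in small intestine, colon and gall bladder and at 7.44 and 2.98 in thymus and trachea. The lists as wholes did not pass in this direction. In thymus tuft 6 of 19 eicosanoid genes were higher and 4 lower (camera adjusted p = 0.493), and 10 of 24 cytokine and receptor genes higher and 1 lower (camera adjusted p = 0.0517). In trachea tuft 4 eicosanoid genes were higher and 4 lower (camera adjusted p = 0.487), and 2 cytokine and receptor genes were higher and 8 lower (camera adjusted p = 0.0252 in the lower direction, and adjusted p = 0.0864 with an estimated correlation). Thymus and trachea together were not tested against the digestive organs. These genes were picked from fixed lists after their values were seen.

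Regroupings of the libraries were planned. The tests on enterocyte genes, thymus and tracheal transcripts were written after the pattern was seen, except the spread of enterocyte ratios and the count of liver, thyroid and pancreas markers. For each result below, 1 of the splits, the real one, reached the real value. Of 100 splits, the real one gave 3469 calls in small intestine (highest other 1209), 3270 in colon (1737), 4265 in gall bladder (1074), 6435 in thymus (2043) and 6147 in trachea tuft (1789). Restricted genes numbered 205 in small intestine (0), 123 in colon (0), 184 in gall bladder (0), 1228 in thymus (1) and 362 in trachea (0). Shared genes numbered 266 (35). The other splits mixed organs within a group, which widens its spread, so lower counts there were built in. They show that the libraries were not all alike, and cannot exclude chance for a single tissue or for the shared genes. Over 35 splits of the colon and small intestine tuft libraries, the real one gave a total of 1660 calls (highest other 188). Every other split again mixed organs within a group, so lower totals were built in there as well. The total shows that these libraries were not all alike, and cannot exclude chance for the difference between colon and small intestine. The 10 splits of the 6 small intestine libraries are too few for a share under 0.05: 2092 and 2235 genes against 0 and 0 in any other.

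Enterocyte genes were not depleted in small intestine tuft libraries: all 20 log2 ratios to the reference lay above 0 (0.08 to 2.26, median 0.65), with 2 called higher. Carry-over of the whole reference epithelium is argued against, because goblet, Paneth and enteroendocrine genes lay -5.27 (log2) from the enterocyte median. The SD of the log2 ratio over the 20 enterocyte genes was 0.46, below all 100 random lists matched on level (median 1.51), as enterocyte RNA or cells alone in the sort could give. The random lists were drawn from all tested genes, so any genes that change together could fall below them. The goblet, Paneth and enteroendocrine genes, with an SD of 1.12, also lay under the median. A low spread therefore cannot decide for carry-over. Carry-over would then need a larger share of enterocyte RNA in the tuft than in the reference libraries, and that share was not measured. Tuft cells with such transcripts of their own remain possible, since no test separated these.

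Thymus tuft had the most restricted genes. Depth and mitochondrial transcripts are argued against: 1120 genes were restricted after thinning and 1185 without mitochondrial genes, against 378 and 375 in the next tissue. Blood cells, which the CD45-negative, EPCAM-positive gate should remove, had few markers restricted to thymus tuft (thymocyte and T cell 1 of 15, B cell 0 of 7, myeloid 1 of 14, erythroid 0 of 6, against 8 of 15 stromal). Over all genes the share was 1228 of 19850, near those of the thymocyte and myeloid lists. Yet most thymocyte and T cell markers and most myeloid markers were called higher in thymus tuft than the mean of the other tissues. A bound set beforehand, more than 2 liver, thyroid or pancreas markers, was met by 3 of 19 (Fgg, Tg, Rnase1), but by 1 to 3 when 1 thymus library was left out, so blood cells are not excluded. Of 17 thymic epithelial markers 11 were restricted, which other thymic epithelial cells in the sort and tuft cells of thymic origin could both give, so these cannot be told apart.

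Tracheal secretory transcripts appeared in other libraries, with Scgb1a1 at 65.8, 33.3 and 0.233 CPM in small intestine tuft libraries 2, 3 and 4 and at 242, 0.318 and 0.699 in gall bladder libraries 1, 3 and 4. The first test compared secretory with other trachea-restricted genes and found 0 of 10 libraries within 3 times of each other and 0 with the secretory genes above; it decided nothing, because the other genes lay at 10.5% of the tracheal level even in small intestine library 4, where secretory genes lay at 0.00191%. A second test, chosen after that, used genes at no more than 0.01% of the tracheal level in the library of the same tissue with the least secretory RNA. Both kinds of gene then lay within 3 times of each other in 3 of 3 libraries (0.321 and 0.338%, 0.166 and 0.298%, 0.873 and 0.421%), and in 0 did secretory genes lie over 3 times above. The medians rested on 7 secretory genes and 20 or 23 other genes. Tracheal RNA or reads carried into those 3 libraries would give such values. They argue against local secretory cells only as far as the other genes are not genes of secretory cells themselves, which was not tested. Thymus tuft, with no clean library, was not covered, and at which step carry-over could occur was not tested.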
